A study of Arabidopsis thaliana with 12 samples.

How the data were processed

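Roots and shoots of Arabidopsis thaliana seedlings were profiled on 12 single-colour Affymetrix arrays, 2 biological replicates in each of 6 groups. Per the labels, plants were raised for 10 days on a control medium and then kept for 5 days on agar from which contaminating metals had been washed. That agar either held 10 µM Fe-HBED, an Fe chelate, or held no added Fe. Tissue was taken at the age of 15 days, 3 h after the lights came on. Wild-type Col-0 was grown with and without Fe. The irt1 mutant, in which the root Fe transporter IRT1 is disrupted, was grown with Fe. Groups and replicate numbers were read from the sample titles.

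The deposited values are log2 expression values, 1 per probe set and array, made by RMA (background correction, quantile normalisation and median polish) per the submitters' processing notes. The version of RMA, and whether roots and shoots were normalised together, are not given in the sources used here. The values ran from 1.9 to 13.5 and were rounded to 1 decimal. Sorted columns differed by at most 0.4, and array medians lay between 5.4 and 5.6. A log2 fold change of a 2-array group therefore moves in steps of 0.05, and log2 fold changes understate changes at levels near the lower end of the scale. The number of arrays limits the precision.

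Of 22810 probe sets, 64 Affymetrix controls were left out of all tests, and 22746 were tested. Gene names came from the platform annotation, which can be old, with symbols updated through Entrez gene IDs to the RefSeq gene table of assembly TAIR10.1. In that annotation 13513 probe sets had 1 gene, 503 had several, and 8730 were not listed and are unnamed here. Of the first, 13436 matched a locus of the RefSeq table, over 13286 distinct loci. The probe set of IRT1 itself is not named in that annotation, so its level is not analysed here under that name. The same holds for many other well-known Fe genes, and list counts below therefore cover the named part of each list.

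Comparisons were made on the deposited log2 values with limma 3.58.1 in R 4.3.3. All 12 arrays entered a single linear model with a mean per group, which leaves 6 residual degrees of freedom, and contrasts were tested with eBayes (no trend, not robust, two-sided). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the 22746 probe sets, with no minimum fold. Adjusted p-values and standard errors (SE) throughout come from this model. Unless stated otherwise, SDs are over the 2 arrays of a group. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so none was run. The 9 contrasts were Fe deficiency and irt1 in each tissue, irt1 against Fe-deficient wild type in each tissue, the difference of each response between tissues, and wild-type roots against wild-type shoots.

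These choices were made before the data were examined, as were the rule for named genes and 15 gene lists. In each of the 4 main comparisons the rule took the 5 highest and 5 lowest log2 fold changes among called probe sets with 1 gene whose groups did not overlap. It added up to 3 called members from each of the first 2 lists and up to 2 from each other list. For irt1 against Fe-deficient wild type and for the tissue differences it took the 5 highest and 5 lowest, and for roots against shoots the 2 highest and 2 lowest. IRT1 was to be reported first and could not be for the reason above. Genes named outside the rule are said to be so or are given as list members.

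The 15 lists held 252 distinct loci, of which 41 were measured by a named probe set. Where a locus had several, the probe set with the highest mean was used. Lists with at least 3 measured members (8 of them) were tested with limma's camera, with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. The heat shock, methionine cycle and nicotianamine, and phosphate starvation lists had 0 measured members. A further 2 lists, of Fe-responsive loci and of photosynthesis and carbon fixation, were written after the annotation had been seen and before any test. Symbol families with at least 8 probe sets, 30 in all, were also tested in the 4 main comparisons, as a choice made after seeing the annotation.

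Fe deficiency and irt1 were each measured against the same wild-type arrays with Fe. The overlap and correlation of the responses were therefore set beside 100 simulations of unchanged groups against shared controls. That overlap was also set beside the overlap of independent lists of the same sizes. The overlap between tissues, which share no arrays, was set beside that of independent lists of the same sizes, although calls in both tissues rest on the same spread per probe set. The model was tested on simulated data for root Fe deficiency over 22746 probe sets, of which 200 were changed. It found 10% of those changed by a log2 of 0.5, 93.8% of those changed by 1 and 100% of those changed by 2. There were 6 false calls and 0 calls of the wrong sign. The simulated noise was normal, with the same spread per probe set in all groups, as the model assumes. These counts therefore do not test whether the pooled spread holds for the measured groups. In the same simulation the list test gave p under 0.05 for 9 of 200 null lists. The simulated probe sets varied independently, while estimated correlations within the fixed and added lists ran from -0.142 to 0.358. The simulation therefore does not test the list test for correlated genes. Alternatives covered the normalisation, a filter on dim probe sets, the arrays in the model, the moderation, the replicate number as a block, array weights, a fold minimum, cross-hybridising probe sets, the list test and leaving out each array in turn. Noise added for the rounding was an alternative chosen after seeing the data.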

Results

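Transcript levels were measured in roots and shoots of 15-day-old Arabidopsis seedlings with 12 arrays, 2 for each of 6 groups. The groups were wild type with Fe, wild type without Fe for 5 days, and the irt1 mutant with Fe, each in roots and in shoots. IRT1 is the main transporter by which roots take up ferrous iron. Replicate arrays correlated with r from 0.991 to 0.996 across probe sets. The difference between replicates had an SD of 0.293 in wild-type shoots with Fe and 0.29 in irt1 shoots, against 0.188 to 0.22 in the other groups. The 12-array model pools these spreads, so its p-values in shoots may be too small. In irt1 shoots, replicate 1 stood apart in the control probe sets for RNA integrity. Its 3' minus 5' log2 difference was 1.6 for GAPDH and 1.9 for actin, against 0.7 to 1 and 1 to 1.7 on the other 11 arrays.

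The tissue labels were checked first, with wild-type plants grown with Fe. AT3G01190 and AT4G15390 were higher in roots by log2 fold changes of 7.35 ± 0.23 and 6.55 ± 0.31 (SE). ECS1 and AT3G05730 were lower in roots, by log2 fold changes of -8.75 ± 0.15 and -8.65 ± 0.12. Of the 22746 probe sets, 7274 were called higher and 5196 lower in roots.

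To ask how wild-type roots respond to a medium without Fe, they were compared with wild-type roots grown with Fe. IMA1 (AT1G47400), which encodes a small peptide of Fe signalling, rose 42.2-fold, from a log2 level of 3.15 ± 0.49 to 8.55 ± 0.07 (SD, n = 2; limma adjusted p = 7.09e-08). S8H (AT3G12900), a scopoletin hydroxylase gene of coumarin synthesis, rose from 4.65 ± 0.21 to 10.05 ± 0.35 (SD, n = 2; limma adjusted p = 2.11e-07). The transcription factor gene bHLH101 rose by a log2 of 4.60 ± 0.20 (SE), the cytochrome P450 gene CYP71B5 by 4.55 ± 0.20 and AT3G61930 by 4.55 ± 0.23, the 5 highest among named probe sets, while the highest pair of unnamed ones had log2 fold changes of 6.25 and 5.75. At the other end, AT1G52820, of the family of oxoglutarate- and Fe-dependent oxygenases, fell from 6.75 ± 0.21 to 3.30 ± 0.00 (SD, n = 2; limma adjusted p = 2.7e-07). AT2G41810, AT5G57785, the photosystem I subunit gene PSAN and AT3G49160 followed among named probe sets, with log2 fold changes of -2.05 ± 0.17, -1.95 ± 0.29, -1.90 ± 0.15 and -1.85 ± 0.14 (SE). The lowest pair of unnamed ones had log2 fold changes of -3.2 and -2.9.

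Among the fixed lists, all 4 measured members of root Fe uptake and mobilisation rose, over all probe sets and adjusted over the list alone, with a median log2 fold change of 3.78 (camera adjusted p = 1.24e-14). They were S8H, CYP71B5, the beta-glucosidase gene BGLU42 (3.00 ± 0.16 SE) and F6H1, a feruloyl-CoA hydroxylase gene of coumarin synthesis (2.40 ± 0.34). IRT1, FRO2, FIT and AHA2, also on that list, were not among the measured members, so its results here and below do not cover them. S8H and F6H1 are also 2 of the 3 measured members of the phenylpropanoid and coumarin list, beside HCT (0.85 ± 0.13). These lists are therefore not independent in any comparison below. Of 10 measured Fe-deficiency regulators 6 rose and 0 fell (7 and 1 adjusted over the list alone; camera adjusted p = 5.18e-11), among them IMA1, bHLH101 and BTSL1 (2.45 ± 0.17), which encodes a hemerythrin E3 ligase. Of 4 Zn and Mn transport genes, MTP8, a Mn transporter, rose by 3.80 ± 0.14 and ZIP9 by 1.70 ± 0.25, and 0 fell (2 and 1 adjusted over the list alone; adjusted p = 0.000389). All 3 measured phenylpropanoid and coumarin genes rose (3 adjusted over the list alone; adjusted p = 1.27e-08). Of 3 root hair markers, the cell-wall genes XTH26 and EXPA18 rose, by 2.35 ± 0.13 and 0.70 ± 0.17 (2 adjusted over the list alone; adjusted p = 5.13e-05).

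Photosynthesis genes were lower in roots without Fe. Of 5 measured members 4 fell (4 adjusted over the list alone; camera adjusted p = 1.91e-08), including PSAN and LHCB4.2 (-1.25 ± 0.14 SE) for an antenna protein of photosystem II. Of 7 chlorophyll and haem genes CHLM and CHLI2 fell, by log2 fold changes of -0.75 ± 0.15 and -0.50 ± 0.10 (4 adjusted over the list alone; adjusted p = 0.00472). With an estimated correlation the adjusted p of this list was 0.0804, while the other lists named so far kept an adjusted p of 0.0138 or lower. The list of Fe storage and Fe-containing proteins had 3 measured members, SAPX, VTL3 and VTL4, with no ferritin gene among them. Of these 3, 0 rose and 0 fell (2 lower adjusted over the list alone; adjusted p = 0.0618). This list is called the Fe storage list below, and its results do not cover ferritin genes. The measured members of the copper, clock, defence and antioxidant lists (CCS and ARPN, GI, PDF1.2a and SAPX) were not called, although SAPX passed adjusted over its list alone (-0.75 ± 0.21). Of the added lists, all 9 Fe-responsive loci rose (9 adjusted over the list alone; adjusted p = 4.97e-32) and all 7 photosynthesis and carbon fixation genes fell (7 adjusted over the list alone; adjusted p = 8.96e-15). With an estimated correlation the camera adjusted p-values of these 2 lists were far larger, at 0.00153 and 0.00182.

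In total 612 probe sets rose and 569 fell in roots without Fe, 400 of them by at least 2-fold, and 578 were named. The total of 1181 became 642 without wild-type Fe-supplied replicate 1, 461 without replicate 2 of that group and 455 without Fe-deficient replicate 2, and 535 in a model of the 6 root arrays. It was 0 in a limma model of only the groups compared (lowest adjusted p 0.0908; 4053 at an unadjusted p under 0.05), so each call here rests on a spread taken from the other groups too. EXPA18 was not called without any 1 of the 4 arrays (adjusted p 0.0633 to 0.335), and CHLM and CHLI2 without Fe-supplied replicate 2 (0.168 and 0.139) or either Fe-deficient array (0.0777 and 0.0752 without replicate 1, 0.127 and 0.0511 without replicate 2).

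**Figure D1:**
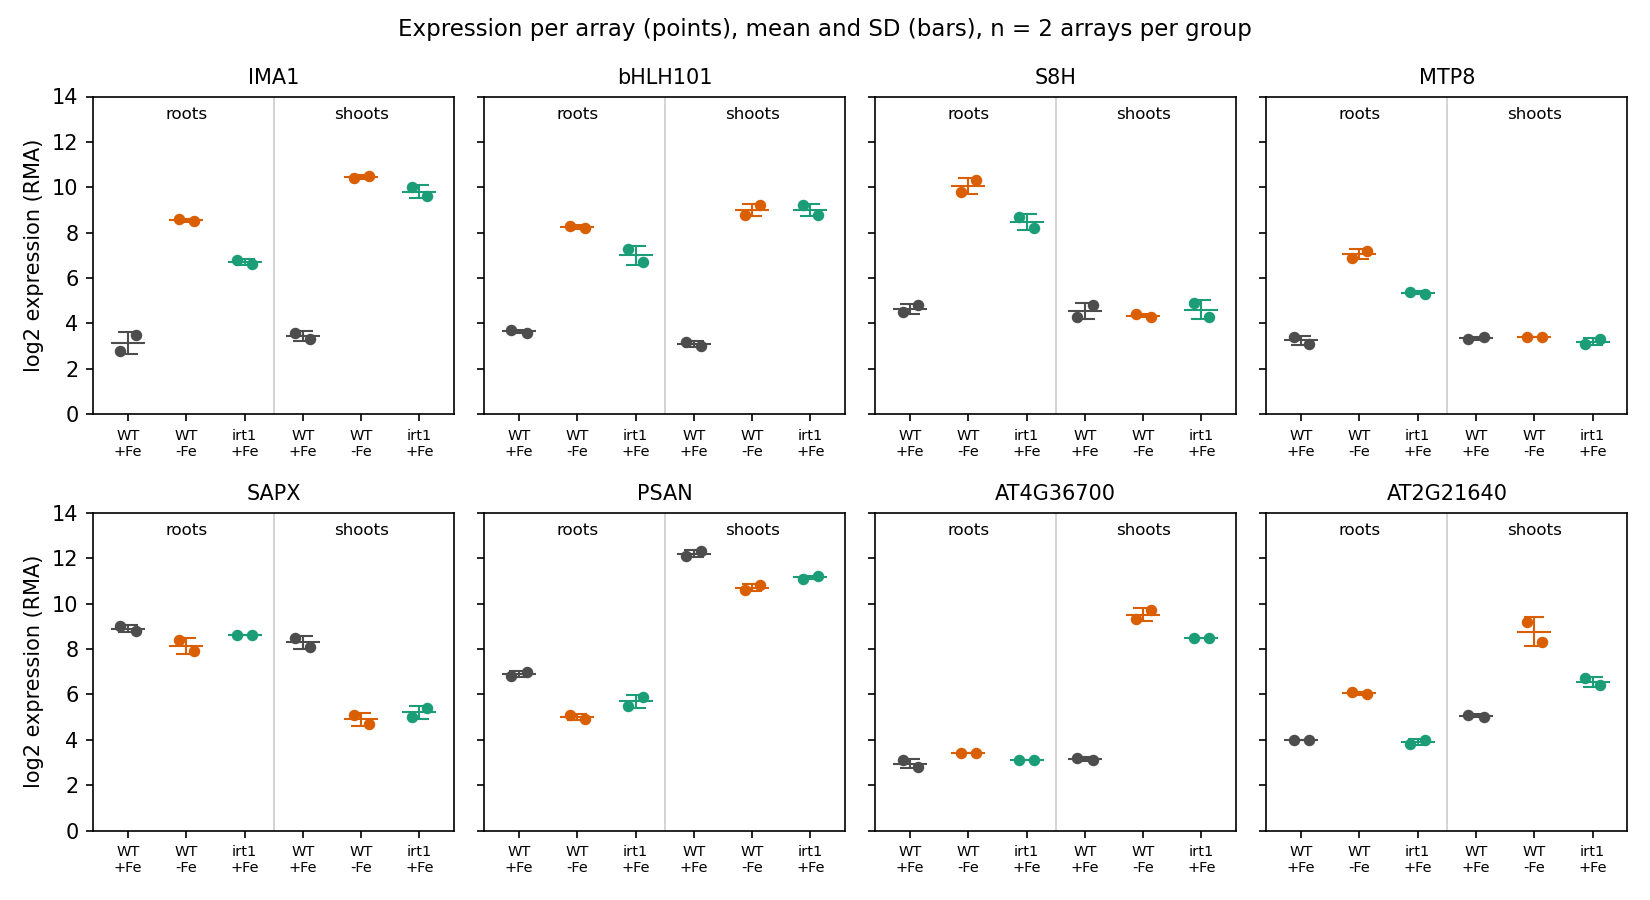
Log2 expression (RMA) of 8 genes on each array, by genotype, Fe supply and tissue. Points are single arrays, and horizontal bars with caps give the mean and SD of the 2 arrays of a group. IMA1 lay at 3.15 in wild-type roots with Fe, 8.55 without Fe and 6.70 in irt1, and at 3.45, 10.45 and 9.80 in shoots.

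To ask what loss of IRT1 changes in roots supplied with Fe, irt1 roots were compared with wild-type roots on the same medium. The highest pair of unnamed probe sets had log2 fold changes of 5.15 and 4.40 and the lowest unnamed one -4.20, and the genes that follow are the extremes among named ones. S8H rose 13.9-fold, to 8.45 ± 0.35 (SD, n = 2; limma adjusted p = 8.6e-06), and IMA1 11.7-fold, to 6.70 ± 0.14 (SD, n = 2; limma adjusted p = 5.6e-06). bHLH101, AT4G19370 and AT3G61930 rose by log2 fold changes of 3.35 ± 0.20, 3.20 ± 0.17 and 3.10 ± 0.23 (SE). AT1G52820 fell by 3.15 on the log2 scale (SE 0.16; adjusted p = 2.64e-06), and AT2G41810, AT4G01390, AT3G56370 and the serine carboxypeptidase-like gene scpl31 had log2 fold changes of -2.25 ± 0.17, -2.20 ± 0.13, -1.85 ± 0.14 and -1.80 ± 0.18.

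Of the 4 Fe uptake and mobilisation genes S8H, F6H1 (1.55 ± 0.34 SE) and BGLU42 (1.25 ± 0.16) rose, while CYP71B5 stood at 0.80 with an adjusted p of 0.0538 (4 adjusted over the list alone; camera adjusted p = 8.31e-09). Of 10 regulators 5 rose and 0 fell, BTSL1 by 1.75 ± 0.17 (6 adjusted over the list alone; adjusted p = 1.06e-07). MTP8 and ZIP9 rose by 2.1 ± 0.14 and 1.35 ± 0.25, 2 of 4 in the Zn and Mn list (2 adjusted over the list alone; adjusted p = 0.00169). Of 3 phenylpropanoid and coumarin genes 2 rose (3 adjusted over the list alone; adjusted p = 3.54e-06), and of 3 root hair markers XTH26 rose, by 1.85 ± 0.13 (1 adjusted over the list alone; adjusted p = 0.000366). The 2 phenylpropanoid and coumarin genes called were S8H and F6H1 again, and HCT was not called (0.35). The plantacyanin gene ARPN of the copper list rose by 1.05 ± 0.15 (1 of 2 members, also adjusted over the list alone). Of 5 photosynthesis genes 4 fell, PSAN by 1.2 and LHCB4.2 by 1.05 on the log2 scale (1 higher and 4 lower adjusted over the list alone; adjusted p = 1.22e-05). The chlorophyll genes PORB and CHLI2 fell by 0.90 and 0.55, 2 of 7 (2 adjusted over the list alone; adjusted p = 0.0012), and the list's adjusted p was 0.05 with an estimated correlation. The other lists named so far kept adjusted p-values of 0.024 or lower with an estimated correlation. The Fe storage list showed 0 calls (0 adjusted over the list alone; adjusted p = 0.275), and GI, PDF1.2a and SAPX were not called. Of the added lists 9 of 9 Fe-responsive loci rose (adjusted p = 2.56e-27) and 7 of 7 photosynthesis and carbon fixation genes fell (adjusted p = 2.93e-13), with the same counts adjusted over the list alone. With an estimated correlation the camera adjusted p-values of these 2 lists were 0.00237 and 0.00247.

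In irt1 roots 428 probe sets rose and 346 fell, 245 by at least 2-fold, and 391 were named. The total of 774 lay between 252 (without irt1 replicate 1) and 359 (without irt1 replicate 2) with 1 array left out, at 317 and 286 without wild-type replicates 1 and 2, at 221 in a model of the root arrays, at 1481 with array weights and at 0 in a limma model of only the groups compared (4258 at an unadjusted p under 0.05). F6H1, ZIP9, PORB and CHLI2 were not called without any 1 of these 4 arrays (adjusted p 0.141 to 0.215, 0.0725 to 0.138, 0.146 to 0.281 and 0.0519 to 0.117).

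To ask how wild-type shoots respond to the medium without Fe, they were compared with shoots grown with Fe. Unnamed probe sets reached log2 fold changes of 6.85 and -6.95, and the genes that follow are the extremes among named ones. IMA1 rose 128-fold, from a log2 level of 3.45 ± 0.21 to 10.45 ± 0.07 (SD, n = 2; limma adjusted p = 6.87e-09). AT4G36700, of the cupin family, rose 81.6-fold, from 3.15 ± 0.07 to 9.50 ± 0.28 (SD, n = 2; limma adjusted p = 9.9e-10). bHLH101, the late embryogenesis abundant family gene AT3G02480 and AT1G12030 rose by log2 fold changes of 5.90 ± 0.20, 5.8 ± 0.28 and 4.70 ± 0.19 (SE). The pyruvate kinase family gene AT3G49160 fell from 6.40 ± 0.28 to 2.30 ± 0.00 (SD, n = 2; limma adjusted p = 1.87e-08), and AT2G36885, the copper amine oxidase family gene AT3G43670, the stromal ascorbate peroxidase gene SAPX and AT5G59400 had log2 fold changes of -3.95 ± 0.18, -3.65 ± 0.15, -3.40 ± 0.21 and -2.70 ± 0.16.

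Of 10 Fe-deficiency regulators 5 rose and 0 fell (5 adjusted over the list alone; camera adjusted p = 1.31e-08), with the bHLH gene PYE at 2.25 ± 0.12 (SE) beside IMA1 and bHLH101. Of 5 photosynthesis genes LHCB4.3 and PSAN fell, by log2 fold changes of -1.95 ± 0.17 and -1.50 ± 0.15 (3 adjusted over the list alone; adjusted p = 1.32e-05). Both lists had an adjusted p of 0.0488 with an estimated correlation. HEME1, for haem and chlorophyll synthesis, fell by 0.65, 1 of 7 in its list (3 adjusted over the list alone; adjusted p = 0.0176, or adjusted p = 0.165 with an estimated correlation). SAPX was the 1 member of 3 that fell in the Fe storage list (1 adjusted over the list alone; adjusted p = 0.0306, or adjusted p = 0.165 with an estimated correlation) and the single measured antioxidant gene. The clock gene GI fell by 1.40 ± 0.15, and CCS, the copper chaperone for superoxide dismutase, rose by 0.85 ± 0.16, both also adjusted over their lists alone. Root Fe uptake, Zn and Mn, phenylpropanoid and root hair lists showed 0 calls, with adjusted p-values of 0.836, 0.482, 0.426 and 0.101 (adjusted over the list alone 0, 1 higher, 0 and 1 lower), and PDF1.2a was not called (-0.90, past the threshold only adjusted over its list alone). Of the added lists 2 of 9 Fe-responsive loci rose (3 adjusted over the list alone; adjusted p = 0.0373, or adjusted p = 0.313 with an estimated correlation) and 1 of 7 photosynthesis and carbon fixation genes fell (2 adjusted over the list alone; adjusted p = 0.00511, or adjusted p = 0.169 with an estimated correlation).

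In shoots without Fe 608 probe sets rose and 498 fell, 330 by at least 2-fold, and 555 were named. The total of 1106 became 525 without wild-type Fe-supplied replicate 2, 350 and 629 without Fe-deficient replicates 1 and 2, 121 in a model of the 6 shoot arrays and 3 in a limma model of only the groups compared (3603 at an unadjusted p under 0.05). CCS was not called without Fe-deficient replicate 1 or 2 (adjusted p 0.0838 and 0.0862), nor HEME1 without Fe-supplied replicate 2 or Fe-deficient replicate 1 (0.108 and 0.154).

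To ask what loss of IRT1 changes in shoots supplied with Fe, irt1 shoots were compared with wild-type shoots. IMA1 rose 81.6-fold, to 9.80 ± 0.28 (SD, n = 2; limma adjusted p = 1.63e-08), and bHLH101 59.7-fold, to 9.0 ± 0.28 (SD, n = 2; limma adjusted p = 2.18e-08). AT4G36700, AT5G05250 and AT3G02480 rose by log2 fold changes of 5.35 ± 0.14, 4.2 ± 0.18 and 4.15 ± 0.28 (SE). The lowest log2 fold changes among named probe sets were those of AT3G49160 (-3.95 ± 0.14), AT2G36885 (-3.75 ± 0.18), AT3G43670 (-3.40 ± 0.15), SAPX (-3.10 ± 0.21) and AT5G59400 (-2.45 ± 0.16), the same 5 named genes as in shoots without Fe. Unnamed probe sets fell further, with log2 fold changes of -6.30 and -5.0 for the lowest pair.

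Of 10 regulators 4 rose, PYE by 1.95 ± 0.12 (SE), and 0 fell (5 adjusted over the list alone; camera adjusted p = 7.79e-09). LHCB4.3 and PSAN fell, by log2 fold changes of -1.75 ± 0.17 and -1.05 ± 0.15, 2 of 5 photosynthesis genes (3 adjusted over the list alone; adjusted p = 3.6e-05). Both lists had an adjusted p of 0.0594 with an estimated correlation. GI fell by 1.1 ± 0.15, CCS rose by 1.05 ± 0.16 and MTP11, a Mn transporter, by 0.55 ± 0.13, and the defensin gene PDF1.2a fell by 1.65 ± 0.36. Of 7 chlorophyll and haem genes 0 were called (3 lower adjusted over the list alone; adjusted p = 0.0368, or adjusted p = 0.234 with an estimated correlation). SAPX was the 1 member of 3 that fell in the Fe storage list (1 adjusted over the list alone; adjusted p = 0.132) and the measured antioxidant gene. The root Fe uptake, phenylpropanoid and root hair lists held 0 calls (0 adjusted over each list alone; adjusted p = 0.694, 0.922 and 0.158), and the Zn and Mn list, with MTP11, had an adjusted p of 0.922. Of the added lists 1 of 9 Fe-responsive loci rose (2 adjusted over the list alone; adjusted p = 0.0374, or adjusted p = 0.313 with an estimated correlation) and 1 of 7 photosynthesis and carbon fixation genes fell (1 adjusted over the list alone; adjusted p = 0.0374, or adjusted p = 0.313 with an estimated correlation).

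In irt1 shoots 438 probe sets rose and 375 fell, 207 by at least 2-fold, and 400 were named. The total of 813 became 299 without irt1 replicate 1, the array that stood apart in the RNA integrity controls, 375 without wild-type replicate 2, 80 in a model of the shoot arrays, 322 with array weights and 0 in a limma model of only the groups compared (2995 at an unadjusted p under 0.05). MTP11 was not called without wild-type replicate 1 or 2 or irt1 replicate 1 (adjusted p 0.118, 0.101 and 0.23), PDF1.2a without wild-type or irt1 replicate 1 (0.136 and 0.236) and CCS without irt1 replicate 1 (0.0533).

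**Figure D2:**
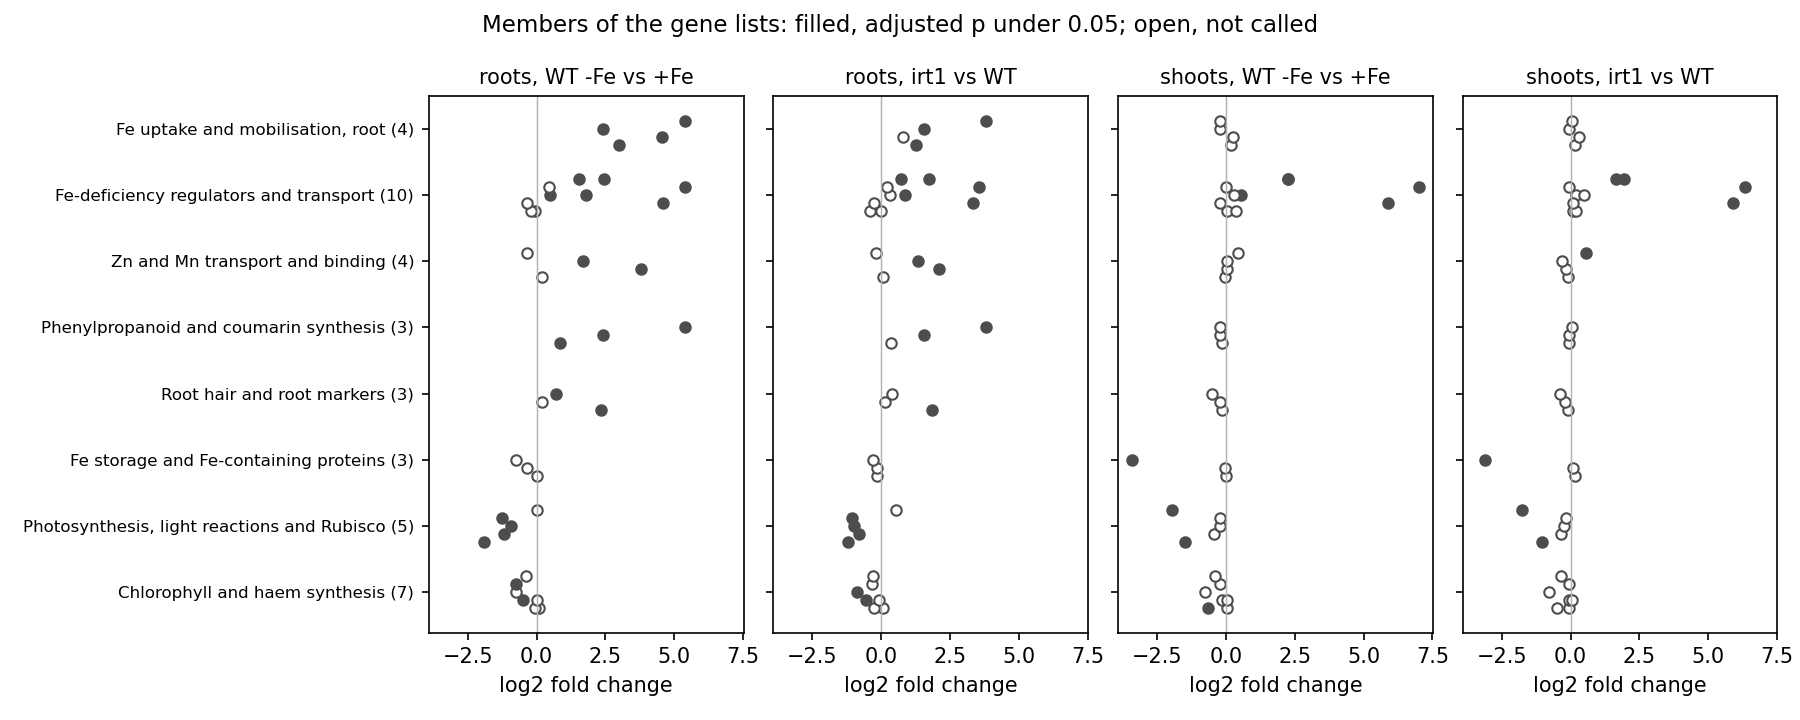
Log2 fold change of each measured member of the 8 tested gene lists (list sizes in parentheses) in the 4 main comparisons. Filled points passed an adjusted p of 0.05 and open points did not. In roots the 4 Fe uptake and mobilisation genes lay between 2.40 and 5.40 without Fe and between 0.80 and 3.80 in irt1, and in shoots between -0.20 and 0.30.

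The responses to irt1 and to Fe deficiency were then set against each other within each tissue. In roots 221 probe sets rose in both and 193 fell in both, and in shoots 225 and 231. In 100 simulations of unchanged groups with shared controls, at most 0 probe sets in roots and 1 in shoots were called in both in 1 direction. Unchanged groups give hardly any calls in either comparison, so that count could hardly have come out otherwise. Independent lists of the same sizes would share 11.5 higher and 8.66 lower probe sets in roots, and 11.7 and 8.21 in shoots. Such lists allow neither for the shared controls nor for the same spread per probe set. The total of 414 in roots became 186 and 162 without wild-type Fe-supplied replicates 1 and 2, 265 without Fe-deficient replicate 2, 157 and 241 without irt1 replicates 1 and 2, and 123 in a model of the root arrays. The total of 456 in shoots became 233 without wild-type Fe-supplied replicate 2, 240 and 298 without Fe-deficient replicates 1 and 2, 216 without irt1 replicate 1, and 68 in a model of the shoot arrays. In limma models of only the groups compared the shared calls numbered 0 in each tissue, since irt1 had 0 calls there (4258 and 2995 at an unadjusted p under 0.05). In the 12-array model 7 probe sets in roots moved in opposite directions, and AT3G53370 in shoots, which lost at least 1 of these calls whichever of the 12 arrays was left out. IMA1, bHLH101, AT4G36700, AT3G49160 and SAPX were among the shared calls in shoots, and S8H, IMA1, bHLH101, MTP8 and AT1G52820 in roots. The log2 fold changes correlated across probe sets with r = 0.69 in roots and 0.79 in shoots, against a mean of 0.50 in simulations of unchanged groups with shared controls. Their covariance was 0.0677 in roots and 0.0883 in shoots, against simulated means of 0.0119 and 0.0118 and a highest value of 0.0124. The simulations gave each probe set a single spread pooled over all groups. Replicates of the shared control differed with an SD of 0.293 in shoots, against 0.188 in roots. The simulated covariances, correlations and shared calls may therefore be too low for shoots. Probe sets are not independent replicates, and the controls were not split, since each part would hold 1 array, so part of the excess may come from the shared controls. Of the 7 opposite calls in roots 3 were named, and without wild-type Fe-supplied replicate 1 none of these 3 was called in both comparisons. In a model of the root arrays 3 of the 7 stayed opposite, all of them unnamed. Of all 7, a probe set with no gene in the annotation used here moved most, and it was 1 of those 3. Whether it measures the disrupted gene itself, in which case its fall in irt1 would be no response, is left open here. It went from 7.80 ± 0.14 in wild-type roots with Fe to 11.75 ± 0.07 without Fe and 3.60 ± 0.14 in irt1 (SD, n = 2; limma adjusted p = 1.44e-07 and 7.76e-07).

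**Figure D3:**
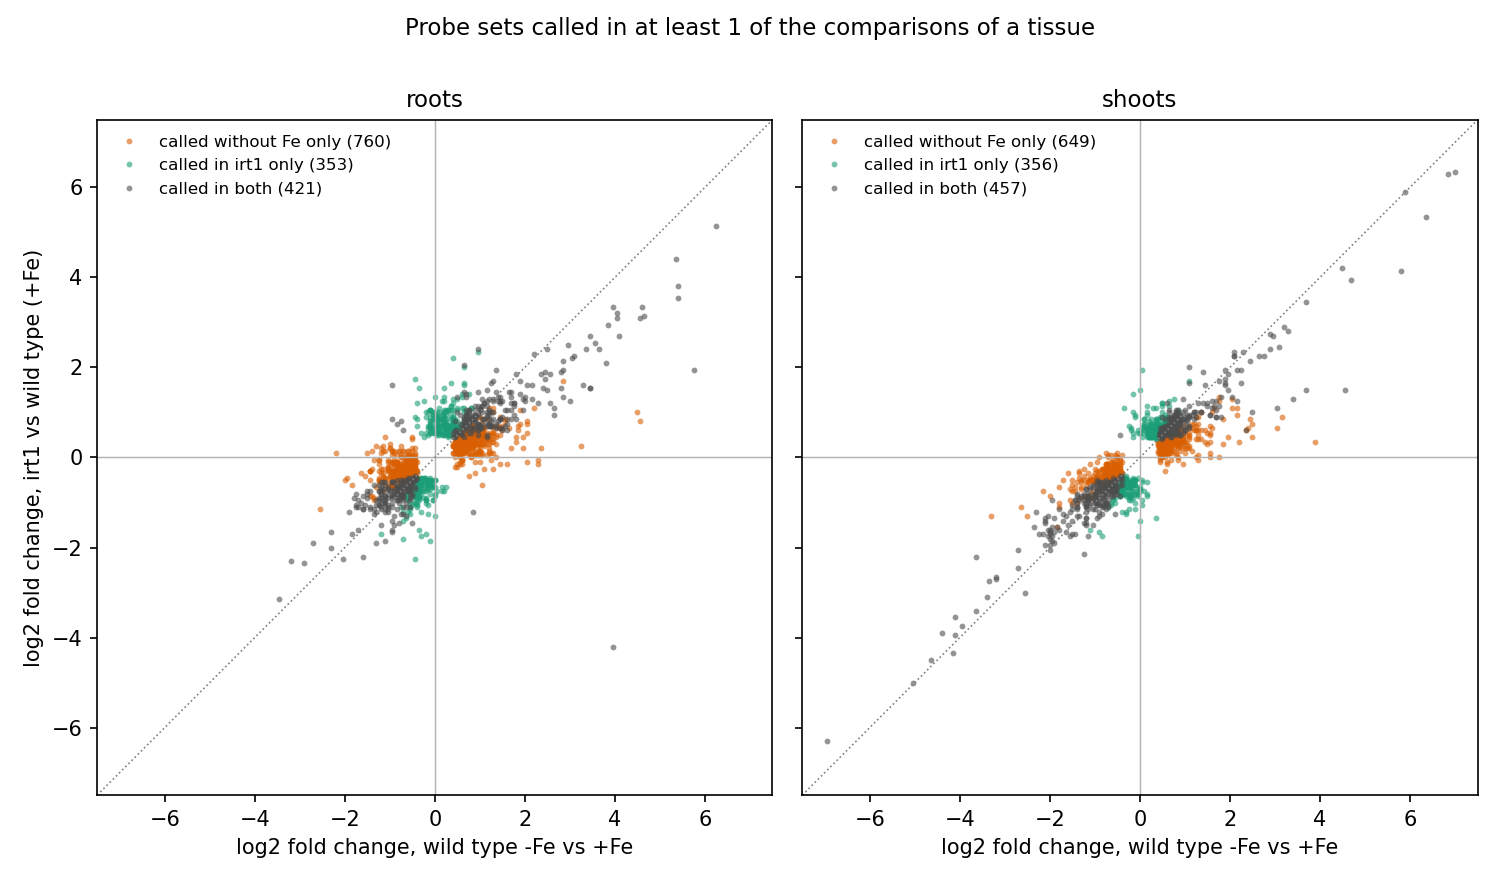
Log2 fold change in irt1 (vertical axis) against log2 fold change without Fe (horizontal axis) for probe sets called in at least 1 of these comparisons, in roots (left) and shoots (right). Colours mark calls without Fe only, in irt1 only or in both, and the dotted line marks equal change. Probe sets called in both lie almost all in the same-sign quadrants, with 7 exceptions in roots and 1 in shoots.

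To test where the responses differ in size, irt1 roots were compared directly with Fe-deficient wild-type roots. The lowest and highest log2 differences, -8.15 and 2.55, belonged to unnamed probe sets, and the genes that follow are the extremes among named ones. The former is the probe set above that may measure the disrupted gene itself. CYP71B5 was lower in irt1 roots, at 4.0 ± 0.00 against 7.75 ± 0.35 (SD, n = 2; limma adjusted p = 3.87e-06). AT4G33720, AT3G02480, AT2G21640 and AT5G19890 were lower by log2 differences of -2.45 ± 0.47, -2.35 ± 0.28, -2.15 ± 0.23 and -2.15 ± 0.18 (SE). AT4G07820, the terpene synthase gene TPS-CIN, AT3G01175, AT5G64120 and the linker histone gene HIS1-3 were higher, by 1.9 ± 0.16, 1.80 ± 0.30, 1.60 ± 0.15, 1.60 ± 0.28 and 1.60 ± 0.26. The Fe uptake and mobilisation genes were lower in irt1 (3 of 4, and 4 adjusted over the list alone; camera adjusted p = 3e-11), as were 4 of 10 regulators (5 adjusted over the list alone; adjusted p = 6.83e-08) and 1 of 3 phenylpropanoid and coumarin genes (3 adjusted over the list alone; adjusted p = 7.18e-05). IMA1 differed by -1.85 and S8H, the 1 phenylpropanoid and coumarin gene called and also on the uptake and mobilisation list, by -1.60. MTP8 differed by -1.70, 1 of 4 in the Zn and Mn list (1 adjusted over the list alone; adjusted p = 0.0108, or adjusted p = 0.0634 with an estimated correlation), and ARPN was higher by 0.75. Of 3 root hair markers 0 were called (1 lower adjusted over the list alone; adjusted p = 0.0353, or adjusted p = 0.0883 with an estimated correlation). The Fe storage and chlorophyll lists held 0 calls (0 adjusted over each list alone; adjusted p = 0.233 and 0.832). Of 5 photosynthesis genes PSAN was higher in irt1, by 0.70 (3 adjusted over the list alone; adjusted p = 0.00116, or adjusted p = 0.0634 with an estimated correlation).

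In total 240 probe sets were higher and 176 lower in irt1 roots than in Fe-deficient roots. The total of 416 became 163 and 97 without Fe-deficient replicates 1 and 2, 116 and 81 without irt1 replicates 1 and 2, 22 in a model of the root arrays and 0 in a limma model of only the groups compared (3014 at an unadjusted p under 0.05). AT5G64120 lost the call without any 1 of these 4 arrays (adjusted p 0.105 to 0.134), TPS-CIN without any but Fe-deficient replicate 1 (0.0516 to 0.128), HIS1-3 without any but irt1 replicate 1 (0.055 to 0.1) and AT4G33720 without any but irt1 replicate 2 (0.144 to 0.181).

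The same comparison in shoots gave fewer calls, with 28 probe sets higher and 65 lower in irt1 than in Fe-deficient wild type. AT2G04050, of the MATE efflux family, stood at 4.0 ± 0.00 in irt1 shoots and at 7.55 ± 0.92 in Fe-deficient shoots (SD, n = 2; limma adjusted p = 0.000417). AT5G51440, a small heat shock protein gene of mitochondria, AT2G21640, AT2G41730 and AT5G09570 were lower by log2 differences of -2.40 ± 0.32, -2.20 ± 0.23, -2.10 ± 0.29 and -1.95 ± 0.22 (SE). AT1G09500, AT2G40960, AT5G26270, AT3G62950 and AT5G64190 were higher, by 1.9 ± 0.12, 1.45 ± 0.18, 1.15 ± 0.21, 1.1 ± 0.19 and 1.05 ± 0.13. No fixed list member was called, with IMA1 at -0.65 and bHLH101 at 0.00, and the lowest list adjusted p was 0.36, for the regulators (3 lower adjusted over the list alone).

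The total of 93 in shoots became 22 and 57 without Fe-deficient replicates 1 and 2, 48 and 51 without irt1 replicates 1 and 2, and 0 in a limma model of the shoot arrays, in which 1607 probe sets had an unadjusted p under 0.05, or of only the groups compared (1949). AT5G26270 lost the call without any 1 of these 4 arrays (adjusted p 0.0739 to 0.409), and AT3G62950 and AT5G51440 without any but Fe-deficient replicate 2 (0.0824 to 0.383 and 0.0543 to 0.103). The call was also lost without Fe-deficient replicate 1 for AT5G64190 (0.0696) and AT2G41730 (0.0736), without Fe-deficient replicate 2 for AT2G40960 (0.0625), without irt1 replicate 1 for AT2G40960 (0.0577) and AT5G64190 (0.0556), and without irt1 replicate 2 for AT2G41730 (0.0662).

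The responses were also compared between tissues, with the difference itself as the test. S8H differed by -5.60 ± 0.35 (SE; shoot minus root log2 fold change) without Fe and by -3.75 ± 0.35 in irt1. An unnamed probe set differed further, by -6.15 without Fe and -5.15 in irt1. AT3G61930, AT5G04730, CYP71B5 and AT4G19370 differed by -4.50 ± 0.33, -4.30 ± 0.35, -4.30 ± 0.28 and -4.05 ± 0.25 without Fe. AT4G36700, AT1G12030 and AT3G02480 responded more in shoots, by 5.90 ± 0.20, 3.55 ± 0.27 and 3.50 ± 0.40 without Fe and by 5.20 ± 0.20, 3.65 ± 0.27 and 4.2 ± 0.40 in irt1. As a list, root Fe uptake and mobilisation responded less in shoots (4 of 4 without Fe, camera adjusted p = 2.12e-12, and 2 of 4 in irt1, adjusted p = 1.39e-05; 4 and 3 adjusted over the list alone). The same held for the phenylpropanoid and coumarin list (3 of 3 and 1 of 3; 3 and 2 adjusted over the list alone; adjusted p = 2.26e-07 and 0.000127) and the root hair list (2 of 3 and 1 of 3; 2 and 2 adjusted over the list alone; adjusted p = 2.63e-05 and 0.0002). The phenylpropanoid and coumarin list shares S8H and F6H1 with the uptake list. The Zn and Mn list had adjusted p-values of 0.00783 and 0.0196 (0.0527 and 0.0879 with an estimated correlation), and the regulators 0.28 without Fe and 0.00893 in irt1 (adjusted p = 0.233 with an estimated correlation). Of the probe sets called in both tissues without Fe 76 rose in both and 106 fell in both, against 16.4 and 12.5 for independent lists, and 15 moved in opposite directions. For irt1 these counts were 42 and 47, against 8.24 and 5.7, and 6. Calls in both tissues use the same spread per probe set, which independent lists do not allow for. Part of the excess may come from that. Without Fe the total of 182 in 1 direction became 107 and 83 without Fe-supplied root replicates 1 and 2, 116 and 83 without Fe-deficient root replicates 1 and 2, 120 without Fe-supplied shoot replicate 2, 99 and 118 without Fe-deficient shoot replicates 1 and 2, and 47 with a model per tissue. For irt1 the total of 89 became 48 and 47 without wild-type root replicates 1 and 2, 43 and 49 without irt1 root replicates 1 and 2, and 23 with a model per tissue.

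In total 697 probe sets differed between tissues in the response to Fe deficiency and 455 in the response to irt1, with 449 and 175 in models of only the groups compared. Leaving out 1 array gave 256 (without Fe-supplied root replicate 2) to 686 for the former and 178 (without irt1 root replicate 1) to 654 for the latter. For the former the count was also 342 without Fe-supplied root replicate 1, 265 without Fe-deficient root replicate 2, and 294 and 394 without Fe-deficient shoot replicates 1 and 2, and for the latter 186 and 179 without Fe-supplied wild-type root replicates 1 and 2, 244 without irt1 root replicate 2, 295 without wild-type shoot replicate 2 and 242 without irt1 shoot replicate 1.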

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

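The tests for shoot material, for the scaling of the arrays, for linkage and for a sequence difference, and the omission of arrays for the photosynthesis genes, were chosen only after the result was seen.

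The response to Fe deficiency differed between shoots and roots for 697 probe sets, and the response to irt1 for 455, each by limma's test of the difference itself. Values in this paragraph and the next are shoot minus root log2 fold changes that passed that test. Without Fe, the difference was -5.60 for S8H, -4.50 for AT3G61930, -4.30 for AT5G04730 and for CYP71B5, -4.05 for AT4G19370, -3.75 for MTP8, -2.80 for BGLU42, -2.60 for F6H1, -2.50 for XTH26, -1.65 for ZIP9 and -1.20 for EXPA18, genes that rose in roots. Genes that fell more in shoots gave -2.65 for SAPX, -2.25 for AT3G49160, -2.20 for AT2G36885, -1.95 for LHCB4.3, -1.85 for AT3G43670, -1.65 for AT5G59400 and -1.50 for GI. The difference was 5.90 for AT4G36700, 3.55 for AT1G12030, 3.50 for AT3G02480, 3.20 for AT2G04050, 1.60 for IMA1 and 1.3 for bHLH101, which rose more in shoots. It was 3.30 for AT1G52820, 2.85 for AT5G57785, 1.95 for AT2G41810 and 1.05 for LHCB4.2, which fell in roots.

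In irt1 the difference was -3.75 for S8H, -3.15 for AT3G61930, -2.85 for AT5G04730, -2.80 for AT4G19370, -2.25 for MTP8, -1.95 for XTH26, -1.65 for ZIP9, -1.40 for ARPN and -1.10 for BGLU42. It was -2.95 for AT2G36885, -2.80 for SAPX, -2.50 for AT3G43670, -2.30 for LHCB4.3, -2.25 for AT3G49160, -1.75 for AT5G59400 and -1.25 for GI. Genes that rose more in shoots gave 5.20 for AT4G36700, 4.2 for AT3G02480, 3.65 for AT1G12030, 2.8 for IMA1, 2.55 for bHLH101, 1.70 for AT5G05250 and 1.25 for PYE. The difference was 2.75 for AT1G52820, 2.30 for AT2G41810, 1.95 for scpl31 and 0.90 for LHCB4.2, which fell in roots.

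Photosynthesis genes were lower in roots without Fe and in irt1 roots, with 11 of 12 measured members called in each and medians of -0.95 and -0.85, although 9 and 4 were called in a model of the root arrays, and 7 in irt1 roots without Fe-supplied replicate 2 or without irt1 replicate 1 or 2. To test the scaling of the arrays, the members' percentile ranks within arrays were compared. These changed by a median of -14.7 points without Fe and -11.6 in irt1, with at most 3.84 between replicate arrays. The values were already quantile-normalised, and sorted columns differed by at most 0.4. Ranks then largely restate the log2 values and could hardly have come out otherwise, so they decide nothing about scaling. Less shoot material in the root samples was also weighed as the whole cause. Only a few transcripts argue against it, and only if that material had the make-up of the shoot samples. The fall would need carry-over at 1.43% of the shoot level. Of 225 other abundant shoot transcripts 17 lay below that on both root arrays, 9 of them by more than 1 log2 unit (median shortfall 2.22). The rest reached it on at least 1 root array, which carry-over would give, as would expression in roots. ECS1 and AT3G05730, already known from the tissue check, were among these 9. The bound of 5 such transcripts was written only after an earlier count had missed its own bound. That count, against the photosynthesis genes' own share of 2.97%, gave 12, short of a bound of 20. Its cut lay close to the later one, so the bound of 5 could hardly have been missed and decides nothing. What argument there is rests on the 9 transcripts alone. Material from a part of the shoot stays open, and an effect of Fe status on plastid genes in roots may contribute and was not tested apart from it.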

How the results depend on the processing

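The noise added for the rounding, and the omission of arrays for shared calls, were chosen only after the result was seen.

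Of 2051 values recomputed for named genes 1837 kept their direction and call, 214 kept the direction and lost the call, and 0 reversed. All 94 named values of 2-group comparisons had no overlap between the arrays, so leaving out 1 array could not reverse them. Changes of moderation, filter or fold minimum leave the fold change itself as it was. The lack of reversals is therefore no test in these cases. Leaving out 1 array ended the call of 22 of 118 named values in at least 1 case. It gave counts of 455 to 873 for root Fe deficiency, 252 to 359 for root irt1, 350 to 1236 for shoot Fe deficiency, 299 to 1105 for shoot irt1, 81 to 163 and 22 to 57 for irt1 against Fe-deficient roots and shoots, 256 to 686 and 178 to 654 for the tissue differences of Fe deficiency and irt1, and 10514 to 11799 for roots against shoots. The lone array of a group is then assumed to vary like the others. The arrays behind these changes are named beside each comparison.

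In a model per tissue the counts, in the order of the 6 comparisons of 2 groups, were 535, 221, 121, 80, 22 and 0, with 1607 probe sets at an unadjusted p under 0.05 for the last. In limma models of only the groups compared they were 0, 0, 3, 0, 0 and 0, with 4053, 4258, 3603, 2995, 3014 and 1949 at an unadjusted p under 0.05, and 449 and 175 for the tissue differences. Fewer samples set the spread in these models, and models of shoot arrays also lose the root arrays, which varied less. Differences between replicates had SDs of 0.293, 0.22 and 0.29 in the shoot groups, against 0.188, 0.219 and 0.203 in the root groups. How much of the drop comes from either was not tested. Array weights gave 1481 for root irt1, 322 for shoot irt1 and 57 for irt1 against Fe-deficient shoots, and the cause was not tested. A minimum of 2-fold left 400, 245, 330, 207, 144 and 50, 463 for the tissue difference of Fe deficiency, 6010 for roots against shoots, and 132 and 142 shared calls in roots and shoots.

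With an estimated correlation the adjusted p of chlorophyll and haem synthesis became 0.0804 and 0.05 in roots without Fe and in irt1 roots, and 0.165 and 0.234 in shoots. Fe storage became 0.165 in shoots without Fe, and the regulators and photosynthesis 0.0594 in irt1 shoots. The test fry gave 0.0422 for root hair markers in shoots without Fe and 0.00612 for Fe storage in irt1 shoots, and the cause was not tested.

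With the replicate number as a block over both tissues the counts were 1335, 862, 1453, 1113, 521 and 134, and 882 and 647 for the tissue differences, and none of the 8 tested fixed lists changed its call in the 4 main comparisons, where lists were run with the block. Deviations of same-numbered arrays correlated from -0.09 to 0.20 over 15 pairs, 8 of them above 0.1. The numbers were not treated as pairing because the labels name no shared batch and not every pair lay above 0.1, and an effect shared by some same-numbered arrays is not excluded. Noise for the rounding gave 1155, 747, 1015, 813, 411 and 93. Low signal limits folds at the lower end of the scale, and no background values were used.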

Other observations

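The tests for linkage and for a sequence difference, the omission of arrays for the mitochondrial loci and for the calls in both tissues, and the symbol families, were chosen only after the result was seen or after the annotation was seen.

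The genes lower in irt1 shoots than in Fe-deficient wild-type shoots included AT2G21640, AT5G51440 and AT5G09570, and a list of 21 loci known from mitochondrial perturbation was written to test a hypothesis. Of 12 measured, the 6 whose values had not been seen had a median log2 difference of -0.93, all 6 were below 0 and 3 were called (limma's camera p = 1.45e-11, or p = 0.0104 with an estimated correlation), and their medians against Fe-supplied wild type were 1.27 without Fe and 0.27 in irt1. Fe-deficient replicate 1 lay above replicate 2 at 11 of the 12 (median 0.85), the median of the 6 was -0.65 without that replicate and up to -1.38 without replicate 2, and their calls numbered 1 and 4 in these cases and 0 without irt1 replicate 1 or 2. The comparison's total of 93 calls became 22 without Fe-deficient replicate 1 and 0 in a limma model of the shoot arrays (1607 at an unadjusted p under 0.05), so that these loci may respond to the medium without Fe more than to loss of IRT1 is a hypothesis that rests in part on 1 array, and 3 of the 12 also rose in irt1 shoots. A fixed loss of the 65 lower transcripts in the mutant line stays open for part of them: their median in irt1 against Fe-supplied wild type was 0, which met the bound written against it, but 20 were called lower in irt1 while 40 rose without Fe, and a median over members that go both ways decided nothing.

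In both tissues 10 probe sets were called between irt1, grown only with Fe, and wild type both with and without Fe, 4 of them higher and 6 lower in irt1, but 0 in limma models per tissue, where irt1 against Fe-deficient shoots gave 0 calls and 1607 probe sets, all 10 among them, had an unadjusted p under 0.05. The number was 5 without Fe-deficient root replicate 1 or 2, irt1 root replicate 2 or Fe-deficient shoot replicate 1, and 6 without irt1 root replicate 1, Fe-deficient shoot replicate 2 or irt1 shoot replicate 1, and of the 6 named only FHIT (-1.70 in roots and -1.75 in shoots, against Fe-supplied wild type), AT3G56370 (-1.85 and -1.35) and AT4G12790 (-0.95 and -1.05) were called whichever array was left out. Linkage to the IRT1 locus is argued against for the named loci on other chromosomes. Of all named loci 0 lay within 400 genes of IRT1, a window set after the result was seen. AT4G12790 is on the same chromosome outside that window, so linkage stays open for it, and the 4 unnamed probe sets were not placed. A sequence difference in the mutant line under the probes or at these loci stays open. In limma's test 0 of the 10 differed between tissues in the irt1 fold (2 at an unadjusted p under 0.05), which a regulated difference could also give.

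Of 30 symbol families, the family RPS, grouped by symbol alone, was the 1 that passed in any of the 4 main comparisons. In roots without Fe 2 of 8 members fell and 0 rose, with a median of -0.53 (camera adjusted p = 0.00685, or adjusted p = 0.265 with an estimated correlation).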
